A study of Mus musculus with 6 samples.

How the data were processed

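Total RNA was extracted from fresh mouse liver, and per the labels' protocols polyadenylated RNA was purified on oligo(dT) beads, fragmented and made into libraries with dUTP in the second strand, which keeps strand information, before paired-end sequencing on an Illumina NovaSeq instrument. Samples were accepted for sequencing on a minimum RNA integrity number, per the labels' protocols. Cutadapt 1.9 and FastQC are named in the submitters' processing notes, as is the mouse genome build GRCm39; the aligner, the counting tool and its use of strand are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene, with a column for each of the 6 libraries. In each library more genes had a count of 4 than of 3 or 5 (879 against 558 and 258 in HFCF replicate 1), so 1 read pair may be worth several counts in this table, which would overstate the counting depth.

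Samples were grouped by their titles into HFCF and OP, with 3 replicates each. Gene symbols came from a table matched on Ensembl identifiers, and 55141 of 55401 identifiers had a symbol. The genome and annotation at hand (GRCm38, GENCODE M21) were of another build than the submitters', so no coordinates are given. GENCODE M21 was used only for exon overlaps between genes, gene classes and transcript lengths. Totals ranged from 46459980 to 61918541 counts. The 3 counts that set the detection floor cover counting error only. SDs were taken over the 3 libraries of a group. Standard errors of log2 fold changes came from the fit described below, which includes the spread between libraries. Replicates were compared within groups by the chi-square statistic per degree of freedom of their counts, over genes with at least 20 counts in a pair. It was 46.2 for HFCF replicates 1 and 2. The other pairs within groups ran from 148 to 350, so no pair agreed within sampling noise.

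The comparison was OP minus HFCF. Genes were kept by edgeR's filterByExpr (17394 of 27893 with any count), libraries were scaled by TMM, and genes were tested two-sided with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. A total of 31 gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested, with adjustment over these 30 lists; camera with an estimated correlation, fry and camera on ranks were run beside it. For a gene at 0 in each library of a group, a lower bound of the fold was computed against 3 counts per library.

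Named genes followed a rule written before the data were examined: per direction, the 10 largest absolute log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is not a predicted-gene name and groups that do not overlap; the members of each list with the smallest p; Pparg, Ppara, Cd36, Fabp4, Cidec, Plin2, Fasn, Scd1, Cpt1a, Srebf1, Cyp7a1, Tnf, Il1b, Col1a1 and Acta2; and the 5 most abundant genes that passed. Not every gene that this rule selects is named in the text. Adipoq, Lpl, Cirbp, Gm20716, Gm49388, Gm45774, Slc13a2os, Plbd2, Gm15690, Hcn3, Thra and the sum with Adnp were chosen after their values were seen. So were the 3 chaperone genes named as examples of a list of 10. That list itself was written before the values of its members were seen.

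Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, robust dispersion estimates, limma-voom without and with quality weights, leaving out each library in turn, a fold change of at least 2 and adjusted p thresholds of 0.01 and 0.1. Added after seeing the data were total counts without scaling factors, leaving out mitochondrially encoded genes and the predicted genes that share their reads, counts divided by 4, and the mitochondrial mRNA share as a covariate.

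The tests were tried on simulated counts for OP against HFCF with 200 changed genes. In addition, the 25 tested genes of cholesterol synthesis were raised 2-fold as a moved list. Among 17394 genes, edgeR's quasi-likelihood test recovered 92 of 100 genes changed 4-fold and 24 of 100 changed 2-fold, and called 10 of 17169 unchanged genes. Each of the set tests called the simulated moved list and 0 of 29 unmoved lists. The simulated genes were drawn independently of each other, while in the data the estimated correlation within a list reached 0.723. The simulation therefore did not test false list calls among genes that move together. Figures were drawn with matplotlib 3.10.9.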

Results

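The series measured gene expression in fresh liver tissue of C57BL/6 mice by poly(A) RNA sequencing, with 1 library per sample. The 3 samples of the HFCF group came from mice on a diet high in fat, cholesterol and fructose, and the 3 samples of the OP group from mice treated with okra polysaccharide, a carbohydrate preparation of the okra plant. The labels of the OP samples do not name their diet, and no group on a standard diet is part of the comparison. The deposited table held 55401 genes, and its totals ranged from 46459980 to 58822973 counts in the HFCF libraries and from 50635853 to 61918541 in the OP libraries. A gene with 0 counts in a library could have been present at up to 0.0471 to 0.0624 CPM (counts scaled to the size of the library), the level of 3 counts, which covers counting error only. Were 1 read pair worth 4 counts, as the values leave open, this level would be 4 times as high. The labels do not say whether the 3 samples of a group were separate animals, so p-values measure the spread between these samples, which may be partly technical. All changes are given for OP relative to HFCF, with n = 3 libraries per group.

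The first comparison asked which genes differed between OP and HFCF livers. Car3, a carbonic anhydrase, rose from 339 ± 185 CPM (SD) to 3280.9 ± 380 CPM. The heat shock gene Hspa1b rose from 1.44 ± 0.666 to 23.2 ± 6.76 CPM. Among the genes that fell, Etnppl, an enzyme of phosphoethanolamine breakdown, went from 264 ± 60.6 to 30.8 ± 10.6 CPM, and Lepr, the leptin receptor, from 24.5 ± 12.7 to 1.65 ± 0.0781 CPM. Of 17394 genes tested, 567 were higher and 603 lower in OP at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 234 of the higher and 358 of the lower genes differed by at least 2-fold. All 1170 had OP libraries that did not overlap the HFCF libraries, as did 31.2% of all tested genes. For a single gene chance gives 10%. Genes that move together can take the share of a split well beyond that, so 31.2% was not tested against chance. HFCF replicates 1 and 2 were the most alike of the pairs within a group (chi-square per degree of freedom 46.2, against 148 to 350 for the others). How far the calls rest on this closeness was not tested. Without HFCF replicate 1, the numbers of genes called were 52 higher and 60 lower, and without HFCF replicate 2 they were 34 and 54. Without OP replicate 1 they were 86 and 117, and without OP replicate 2 they were 313 and 348. With the share of counts in mitochondrial mRNAs as a covariate, an alternative chosen after seeing the data, they were 110 and 97. That share averaged 18.3 ± 4.01% in HFCF and 9.31 ± 4.44% in OP, so it went largely with the group. Share and group then compete for the same difference. A value that shrinks with this covariate therefore cannot be laid to mitochondrial content.

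Among the genes with the largest log2 fold changes under the rule fixed for named genes, those higher in OP included Cyp2b9, a cytochrome P450 (7.08 ± 1.17, SE), the transporter genes Slc22a27 (4.58), Slc22a29 (3.82) and Slc22a26 (3.47), Hspa1a (4.37), Hspa1b (4.01), Aacs, an acetoacetyl-CoA synthetase (3.43), Themis (3.38) and Car3 (3.28). Those lower included Adnp (-6.30), Asns, the asparagine synthetase (-4.11), Lepr (-3.89), Cux2 (-3.85), the citrate and dicarboxylate transporter genes Slc13a2 (-3.35) and Slc13a5 (-3.34), Fst, which encodes follistatin (-3.12), Etnppl (-3.10), the globin gene Hbb-bt (-3.07) and Cib3 (-3.00). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p ranged from 0.00266 for Etnppl to 0.0466 for Slc22a29. Hspa1a, Hspa1b, Car3, Lepr, Cux2, Fst and Etnppl kept an adjusted p under 0.05 whichever library was left out. Slc22a27 lost it without HFCF replicate 2 or OP replicate 1, Themis without HFCF replicate 1 or OP replicate 1, and Slc13a2 without HFCF replicate 1. Cyp2b9, Slc22a26, Adnp, Slc13a5, Hbb-bt and Cib3 lost it without HFCF replicate 1, HFCF replicate 2 or OP replicate 1, Aacs without those or HFCF replicate 3, Asns without any library but HFCF replicate 3, and Slc22a29 whichever library was left out. Without HFCF replicate 1 the log2 fold change of Asns was -2.39, and without OP replicate 3 that of Aacs was 2.28. Hspa1a and Hspa1b are near-identical copies, as are the Cyp2b genes and the globin genes, so the split of reads between copies is uncertain. Slc13a2 overlaps Slc13a2os on the opposite strand, which fell too (-7.28), and use of strand in the counting is not given in the sources used here.

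**Figure D1:**
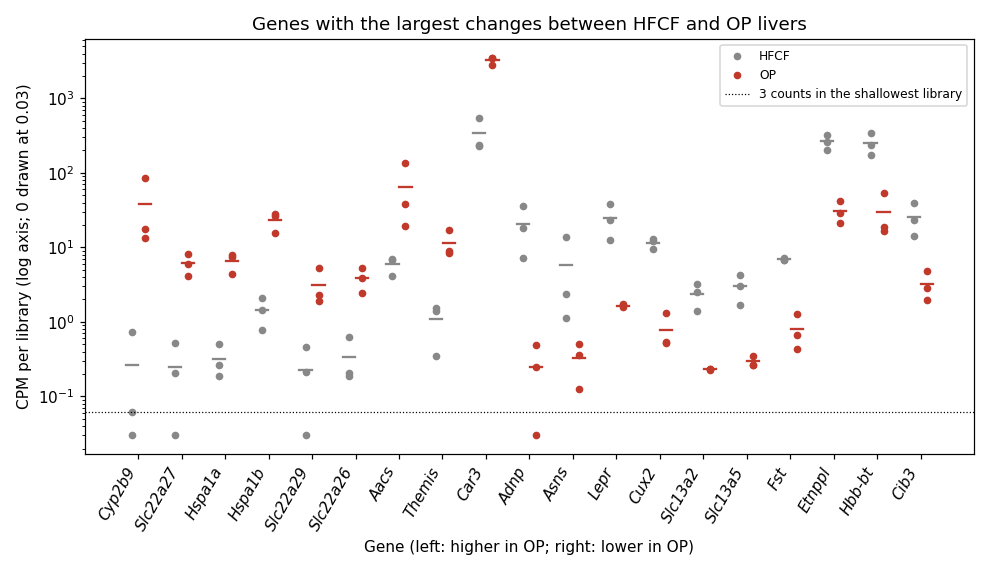
CPM per library on a log axis for genes among those with the largest changes, HFCF in grey and OP in red, with a bar at each group mean. Each gene's OP libraries lie on one side of its HFCF libraries; Car3 ran from 229 to 552 CPM in HFCF and from 2842 to 3508 CPM in OP.

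The count for Adnp, a chromatin regulator gene, depended on a neighbour. In GENCODE M21, Adnp shares 4187 exon bases on the same strand with the predicted gene Gm20716. The HFCF libraries held 1748, 874 and 439 counts for Adnp and 0, 1653 and 2512 for Gm20716, and the OP libraries held 15, 31 and 0 for Adnp and 4617, 4887 and 4203 for Gm20716. Summed, the 2 genes were higher in OP by 0.82 ± 0.169 (log2, SE; adjusted p = 0.0294 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), so the fall of Adnp alone turned to the opposite sign when its overlapping gene was added. This sum was chosen after the values of Adnp were seen.

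**Figure D2:**
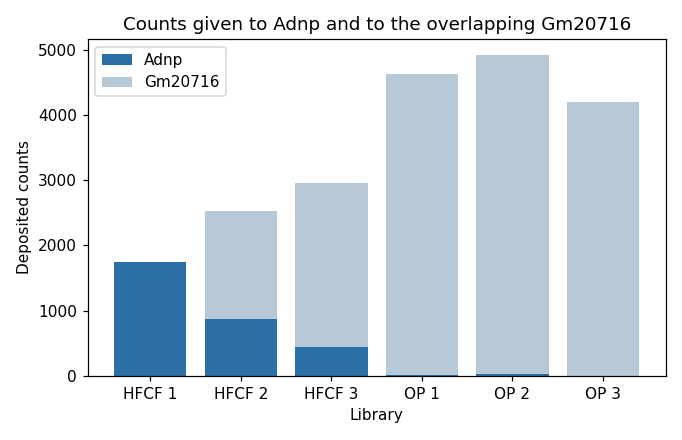
Deposited counts per library given to Adnp (dark) and to Gm20716 (light), stacked. The sum ran from 1748 to 2951 counts in HFCF and from 4203 to 4918 in OP, while the part given to Adnp ran from 439 to 1748 in HFCF and from 0 to 31 in OP.

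PPAR-gamma signalling is named in the title of the series, so its target genes were the first fixed list. Pparg itself, the gene of this nuclear receptor, rose from 4.92 ± 1.91 to 13.1 ± 4.45 CPM, a log2 fold change of 1.41 ± 0.341 (SE). Mogat1, an acyltransferase of triglyceride synthesis, rose by 2.32, the lipid droplet gene Plin4 by 2.22, Agpat2 by 1.04 and Acsl1, an acyl-CoA synthetase, by 0.80. These 5 of 23 tested members rose and none fell, and adjusted over the list alone 9 rose and 2 fell. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.0125 for Agpat2 and Mogat1 to 0.0467 for Pparg. Cd36, a fatty acid transporter gene, was at 17.4 ± 13.8 and 61.8 ± 17.6 CPM (adjusted p = 0.0624 in the same edgeR test), and Plin2 at 357 ± 70.2 and 657 ± 165 CPM (adjusted p = 0.0541); the log2 fold changes of Fabp4 (0.80 ± 0.664) and Cidec (0.30 ± 0.281) did not pass. The list's median log2 fold change was 0.80, with a camera adjusted p = 0.00105, and adjusted p = 0.647 with an estimated correlation; it was 0.45 without HFCF replicate 2 and 0.37 without OP replicate 2. The list adipocyte markers lay on the same side, with all 6 tested members above 0, a median of 1.49 and a camera adjusted p of 0.0588, and Adipoq, Lpl and Fabp4 stand in both lists. That median was 0.82 without OP replicate 2, 0.99 without HFCF replicate 2 and 0.42 with the mitochondrial share as a covariate. Without HFCF replicate 3 it was 5.07 as fitted and 2.70 with the 2 members then at 0 in HFCF set at their bounds. The list passed without HFCF replicate 3 (camera adjusted p = 0.0108) or OP replicate 1 (0.00391), and with upper quartile scaling (0.041), no low-count filter (0.00374) or mitochondrial genes left out (0.0485), in a range of 0.00374 to 0.681 over its alternatives. Adipoq had 0, 0 and 18 counts in the HFCF libraries and 0, 150 and 45 in the OP libraries, and Lpl, a lipoprotein lipase, had 903, 1171 and 2501 against 678, 5177 and 740, with OP replicate 2 the highest for both. Pparg kept its call only without HFCF replicate 3 (log2 fold changes of 1.10 to 1.70 over the 6 libraries left out), Mogat1 lost it without HFCF replicate 1 or 2, Agpat2 without these or OP replicate 1, Acsl1 also without OP replicate 2 and Plin4 also without OP replicate 3. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Pparg also missed the threshold with RLE scaling (adjusted p = 0.0506), no low-count filter (0.0689), mitochondrial genes left out (0.0509) or the mitochondrial share as a covariate (0.16), with adjusted p of 0.000953 to 0.186 over all its alternatives, the lowest with DESeq2. With that covariate the PPAR-gamma list median was 0.32 and its camera adjusted p 0.098.

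**Figure D3:**
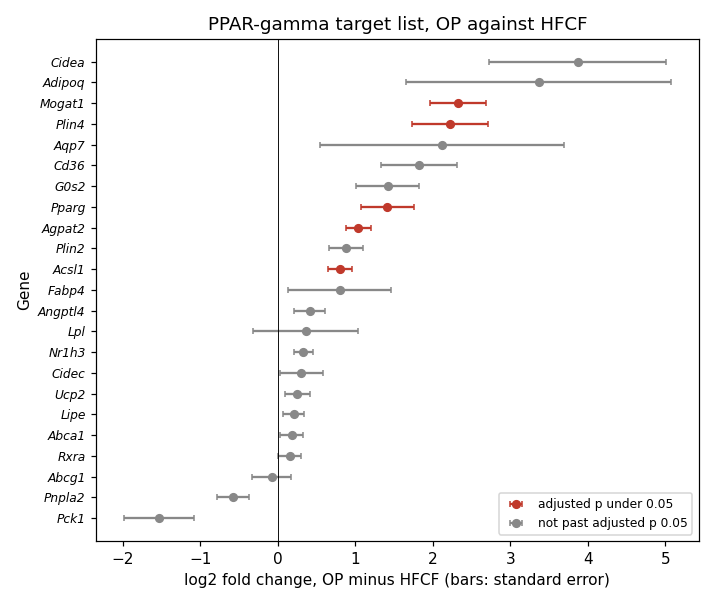
log2 fold change (OP minus HFCF) of the 23 tested members of the PPAR-gamma list, with bars for the standard error; red marks the 5 members with an adjusted p under 0.05. Mogat1 (2.32), Plin4 (2.22), Pparg (1.41), Agpat2 (1.04) and Acsl1 (0.80) are the members that passed.

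Of 25 tested genes of cholesterol synthesis, 9 rose, none fell and 16 did not pass. Among those that rose were Hmgcs1, the HMG-CoA synthase, from 50.2 ± 3.03 to 144 ± 8.13 CPM, and Nsdhl from 6.38 ± 0.136 to 27.0 ± 7.43 CPM; Cyp51 rose by 1.88 (log2). Adjusted over the list alone, 16 rose and none fell. The list's median was 0.79 (camera adjusted p = 1.17e-07, and adjusted p = 0.647 with an estimated correlation). Hmgcs1 and Nsdhl kept their calls whichever library was left out, and Cyp51 lost its call without HFCF replicate 1 or 2. With the mitochondrial share as a covariate the list median was 0.16 (camera adjusted p = 0.0657). Cyp51 was then at 1.03, Nsdhl at 1.81 and Hmgcs1 at 1.515. Their adjusted p were 0.114, 0.0523 and 0.02 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so only Hmgcs1 kept its call.

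In the list for de novo lipogenesis, 4 of 23 tested genes rose and none fell. Thrsp, a gene induced with lipogenesis, rose from 9.24 ± 0.406 to 70.2 ± 31.5 CPM, and Pklr, the liver pyruvate kinase, from 30.6 ± 1.22 to 54.3 ± 2.47 CPM; Dgat2 rose by 0.96 (log2). Fasn, the fatty acid synthase, was at 39.2 ± 6.19 and 71.0 ± 21.5 CPM, Srebf1 at 62.6 ± 4.31 and 80.5 ± 2.42 CPM and Scd1 at 1434 ± 768 and 1845 ± 709 CPM, with adjusted p of 0.0606, 0.12 and 0.628 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 11 rose. The median was 0.36 (camera adjusted p = 0.00428, and adjusted p = 0.681 with an estimated correlation). The list median was 0.58 without HFCF replicate 3, and 0.023 with the mitochondrial share as a covariate (camera adjusted p = 0.666). Thrsp kept its call whichever library was left out, while Pklr (0.78 to 0.86) and Dgat2 (0.85 to 1.10) lost it without HFCF replicate 1, HFCF replicate 2 or OP replicate 1. Pklr overlaps Hcn3 on the opposite strand, which rose too (1.45).

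The list of PPAR-alpha targets and fatty acid oxidation had 8 of 30 tested members higher and 1 lower. Vnn1 rose from 61.7 ± 1.72 to 182 ± 19.0 CPM, Fabp1, the liver fatty acid binding protein, from 2592 ± 510 to 6164 ± 628 CPM, and Acaa1b, a peroxisomal thiolase, from 1752 ± 44.1 to 3270 ± 479 CPM. Ehhadh, a peroxisomal enzyme of the same pathway, fell from 887 ± 64.7 to 350 ± 68.0 CPM. Ppara (-0.34 ± 0.141) and Cpt1a (-0.17 ± 0.158) did not pass the test. Adjusted over the list alone, 13 rose and 1 fell. The median log2 fold change was 0.45 (camera adjusted p = 0.000561, and adjusted p = 0.681 with an estimated correlation), and 0.02 with the mitochondrial share as a covariate (camera adjusted p = 0.974); it was 0.29 without OP replicate 2. Vnn1 kept its call whichever library was left out; Ehhadh (-1.48 to -1.20) lost it without HFCF replicate 1 or 2, Fabp1 (1.14 to 1.42) without these or OP replicate 1, and Acaa1b (0.78 to 0.97) also without OP replicate 2.

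Of 19 lipoprotein genes tested, 4 rose, none fell and 15 did not pass, and adjusted over the list alone 10 rose. Apoe, among the most abundant transcripts that passed, went from 14916 ± 1788 to 27580 ± 948 CPM, Apoc3 from 1629 ± 83.7 to 2662 ± 275 CPM, Sar1b from 82.2 ± 12.4 to 162 ± 14.8 CPM and Lipc, the hepatic lipase, from 90.9 ± 5.34 to 149 ± 2.30 CPM. The median was 0.57 (camera adjusted p = 0.000271, and adjusted p = 0.647 with an estimated correlation). Ttr, the abundant thyroid hormone carrier of plasma, rose by 1.13 ± 0.203. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 212 ± 47.0 to 96.06 ± 10.97 CPM and Hsd3b7, a later enzyme of that pathway, rose from 354.5 ± 25.3 to 616 ± 117 CPM. They were the 2 of 21 bile acid genes that passed, against 4 higher and 2 lower adjusted over the list alone, and that list's camera adjusted p was 0.189. Without HFCF replicate 1, HFCF replicate 2 or OP replicate 1 none of Apoe, Apoc3, Sar1b, Lipc, Ttr, Cyp7a1 and Hsd3b7 kept its call, with log2 fold changes over all 6 libraries left out of 0.77 to 0.98 for Apoe and -1.29 to -0.97 for Cyp7a1; Apoe and Apoc3 also lost it without OP replicate 2, Apoe with RLE scaling and Hsd3b7 without HFCF replicate 3. Hsd3b7 shares exon bases on the same strand with the predicted gene Gm49388, which was not tested.

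Among periportal hepatocyte genes, Sds, the serine dehydratase, fell from 314 ± 53.1 to 48.6 ± 13.9 CPM, Hal, the histidine ammonia-lyase, from 344 ± 58.2 to 119 ± 29.2 CPM and Sdsl from 16.1 ± 3.84 to 6.19 ± 1.87 CPM. Of 14 tested periportal genes 6 fell and none rose, and adjusted over the list alone 8 fell and 1 rose. The median was -0.96 (camera adjusted p = 0.00105, and adjusted p = 0.681 with an estimated correlation). Of 14 pericentral genes 3 rose and none fell, namely Lect2 (71.6 ± 11.6 to 203 ± 23.0 CPM), Rgn (log2 fold change 0.82) and Gulo (0.63), and adjusted over the list alone 4 rose; the median was 0.36 (camera adjusted p = 0.00153, and adjusted p = 0.647 with an estimated correlation). Sds and Etnppl kept their calls whichever library was left out, as did Lect2, while Hal (-1.63 to -1.34) lost it without HFCF replicate 1 or 2, Sdsl without these or OP replicate 1, Gulo also without OP replicate 2 and Rgn also without OP replicate 2 or 3. Sds overlaps Plbd2 (-0.78) and the predicted gene Gm15690 (-2.97) on the opposite strand, and both fell too.

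In the list for gluconeogenesis and insulin signalling, 3 of 17 tested genes fell and 1 rose. Ppargc1a, a coactivator of gluconeogenic transcription, fell from 23.6 ± 1.86 to 4.96 ± 0.624 CPM, Sik1 from 33.8 ± 5.77 to 14.4 ± 2.48 CPM and Irs2, an insulin receptor substrate, from 25.5 ± 6.87 to 11.9 ± 1.60 CPM, while Foxo1 rose from 15.3 ± 1.53 to 27.2 ± 6.24 CPM. Adjusted over the list alone, 8 fell and 1 rose. The median was -0.41 (camera adjusted p = 0.00822, and adjusted p = 0.647 with an estimated correlation). Ppargc1a kept its call whichever library was left out, and Sik1 (-1.36 to -1.10), Irs2 and Foxo1 (0.63 to 0.94) lost it without HFCF replicate 1, HFCF replicate 2 or OP replicate 1, Foxo1 also without HFCF replicate 3.

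Xenobiotic enzymes moved in both directions, with 5 of 18 tested members higher and 3 lower, and 7 and 4 adjusted over the list alone. Cyp3a25 fell from 1873 ± 30.7 to 674 ± 29.3 CPM and Gstp1, a glutathione transferase with close copies, from 1987 ± 94.1 to 711 ± 122 CPM, while Aldh1a1, a retinal dehydrogenase, rose from 736.5 ± 130 to 1604.5 ± 149 CPM. The median was 0.35, also with Cyp2b13 set at its bound (camera adjusted p = 0.0427, and adjusted p = 0.681 with an estimated correlation); the call was lost without HFCF replicate 1, HFCF replicate 2, OP replicate 1 or OP replicate 3. Of 11 female-biased liver genes 4 rose and 2 fell, and 5 and 2 adjusted over the list alone. Hao2 had no counts in any HFCF library and 1.25 ± 0.547 CPM in OP, at least 21.6-fold higher than 3 counts per library, and Cyp2b13 was likewise at least 9.40-fold higher; both bounds would be 4 times lower were 1 read pair worth 4 counts. Prlr, the prolactin receptor, rose by 0.93, and Cux2, a female-biased transcription factor, fell from 11.4 ± 1.72 to 0.787 ± 0.444 CPM. This list had a median of 0.93, also with those 2 genes at their bounds, and a camera adjusted p of 0.189. Over its alternatives the median ran from 0.033 to 1.245. Among 14 male-biased genes none rose and 2 fell, Gstp1 and C6 (-0.79), against 1 higher and 4 lower adjusted over the list alone, with a median of -0.23 and a camera adjusted p of 0.0737. Cyp3a25, Gstp1 and Cux2 kept their calls whichever library was left out; Aldh1a1 and Prlr (0.77 to 1.04) lost it without HFCF replicate 1, HFCF replicate 2 or OP replicate 1, C6 also without HFCF replicate 3 or OP replicate 2, and Hao2 without OP replicate 1.

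Of 18 NRF2 and antioxidant genes 2 rose, Nfe2l2 from 60.4 ± 3.94 to 108 ± 22.7 CPM and Sod1 from 803 ± 120 to 1362.5 ± 92.4 CPM, none fell, and 5 rose adjusted over the list alone; the median was 0.34 (camera adjusted p = 0.00686, and adjusted p = 0.681 with an estimated correlation), and 0.018 with the mitochondrial share as a covariate (camera adjusted p = 0.37). In the list for endoplasmic reticulum stress and the integrated stress response, 3 of 21 genes rose and 2 fell, against 7 and 3 adjusted over the list alone, with a camera adjusted p of 0.12. The transcription factor gene Ddit3 rose by 1.51 and the chaperone gene Hspa5 by 0.74, while Trib3 fell by 1.88 and Asns by 4.11 on the log2 scale. Asns was at -2.39 without HFCF replicate 1 and -1.47 with the mitochondrial share as a covariate, and kept its call only without HFCF replicate 3. Trib3 lost its call without HFCF replicate 2 or OP replicate 1, and Ddit3, Hspa5, Nfe2l2 (0.66 to 0.97) and Sod1 (0.66 to 0.89) without HFCF replicate 1, HFCF replicate 2 or OP replicate 1, Nfe2l2 also without HFCF replicate 3 and Sod1 without OP replicate 2. Nuclear genes of oxidative phosphorylation had 0 of 24 members past the test in edgeR's quasi-likelihood fit, also adjusted over the list alone, yet 22 lay above 0, with a median of 0.37 (camera adjusted p = 0.00105, and adjusted p = 0.681 with an estimated correlation). In the same edgeR fit 10 members had an unadjusted p under 0.05, and limma-voom called 1, DESeq2 5 and limma-voom with quality weights 11. Uqcrc2 was at 101 ± 16.4 and 160 ± 23.5 CPM and Ndufa9 at 86.9 ± 15.9 and 131 ± 9.62 CPM. The median of this list was 0.24 without OP replicate 2 and -0.064 with the mitochondrial share as a covariate.

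Among inflammatory genes, the chemokines Cxcl10 (1.80 ± 0.529 to 5.65 ± 1.901 CPM) and Cxcl9 (3.21 ± 1.27 to 9.56 ± 3.58 CPM) rose. They were the only members past the test of 21 tested, over all genes and adjusted over the list alone. Tnf was at 0.531 ± 0.202 and 0.574 ± 0.170 CPM and Il1b at 1.23 ± 0.246 and 1.80 ± 0.541 CPM, both short of the threshold. The median was 0.44 (camera adjusted p = 0.0216, and adjusted p = 0.647 with an estimated correlation), and the call was lost without OP replicate 3. Of 23 acute phase genes 4 rose and 3 fell, and 6 and 4 adjusted over the list alone, with a camera adjusted p of 0.189. Steap4 rose by 1.38 and Saa2 by 1.13, and the metallothionein genes Mt1 and Mt2 fell by 1.92 and 2.80. Of 23 interferon-stimulated genes 3 rose, among them Ifit1 (0.92) and Isg15 (0.76), and Mx1 fell (8.77 ± 1.56 to 4.40 ± 0.488 CPM), with the same counts adjusted over the list alone and a camera adjusted p of 0.186. Mt2 kept its call whichever library was left out, and each of the other genes named here as rising or falling lost it without HFCF replicate 1, HFCF replicate 2 or OP replicate 1, such as Cxcl10 (1.42 to 1.91) and Cxcl9 (1.27 to 1.91), which also lost it without OP replicate 3. Mt2 overlaps Gm45774 on the opposite strand, which fell too (-6.19).

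Markers of other cell types were examined for changes in tissue makeup. The 4 globin genes fell, Hba-a1 from 324 ± 100 to 66.4 ± 25.6 CPM and Hbb-bs from 471 ± 153 to 71.5 ± 48.3 CPM. Of 6 erythroid genes 4 fell and none rose, against 5 lower and 1 higher adjusted over the list alone, with a median of -2.41 (camera adjusted p = 0.00153, and adjusted p = 0.647 with an estimated correlation). Neutrophil markers had 0 of 5 past edgeR's test, also adjusted over the list alone, and a median of -1.24 (camera adjusted p = 0.0255, and adjusted p = 0.647 with an estimated correlation). S100a9 was at 2.26 ± 0.793 and 0.695 ± 0.451 CPM and S100a8 at 1.40 ± 0.548 and 0.592 ± 0.363 CPM; this list's call was lost without HFCF replicate 1 or 2 or OP replicate 1 or 2, with medians of -1.69 to -0.60, the smallest in size without HFCF replicate 2. Fibrosis and stellate cell genes had 0 of 23 past edgeR's test, also adjusted over the list alone, with Col1a1 at 4.86 ± 3.59 and 4.38 ± 1.65 CPM, Acta2 at 1.72 ± 0.998 and 2.37 ± 1.56 CPM and a camera adjusted p of 0.979. No member passed, over all genes or adjusted over the list alone, among 13 Kupffer cell markers (Clec4f at 137 ± 34.9 and 89.4 ± 14.9 CPM; camera adjusted p = 0.193), 13 endothelial markers (Stab2 at 71.8 ± 24.0 and 44.7 ± 13.8 CPM; 0.682) and 18 T, B and NK cell markers (Igkc at 11.5 ± 0.783 and 37.8 ± 38.3 CPM; 0.189). At an unadjusted p under 0.05 in edgeR's test there were 2 neutrophil, 2 fibrosis, 2 Kupffer cell, 0 endothelial and 4 T, B and NK cell genes. Limma-voom called none in these lists, DESeq2 called 1 neutrophil and 2 Kupffer cell genes, and limma-voom with quality weights called 2 neutrophil, 2 Kupffer cell, 1 endothelial and 2 T, B and NK cell genes. Cd9 alone fell (-0.90) among 15 markers of recruited macrophages, Krt23 alone rose (1.75) among 9 cholangiocyte markers and Adipor2 alone rose (1.12) among 6 adipocyte markers, with camera adjusted p of 0.609, 0.397 and 0.0588. The last list had 2 members higher adjusted over the list alone, and the former lists 1 each. Adipor2 had 5707, 5413 and 9673 counts in the HFCF libraries, where Adipoq had 0, 0 and 18. The rise of Adipor2 therefore does not speak for more adipocytes. Cfd, an adipocyte gene, was at 1.14 ± 1.89 and 33.9 ± 26.2 CPM without passing. Cela1 rose by 1.19, also adjusted over the list alone. It was 1 of 2 pancreatic acinar genes tested, too few for a list test, and the other, Cela2a, was at -2.13 without passing. Acinar genes such as Pnlip, Cpa1, Cpb1, Ctrb1 and Prss2 had 0 counts in all 6 libraries. The rise of Cela1 therefore does not speak for pancreatic tissue. Hba-a1 (-2.63 to -2.06) lost its call without HFCF replicate 1 or 2, and Hbb-bs, Cd9, Krt23, Adipor2 and Cela1 without these or OP replicate 1.

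**Figure D4:**
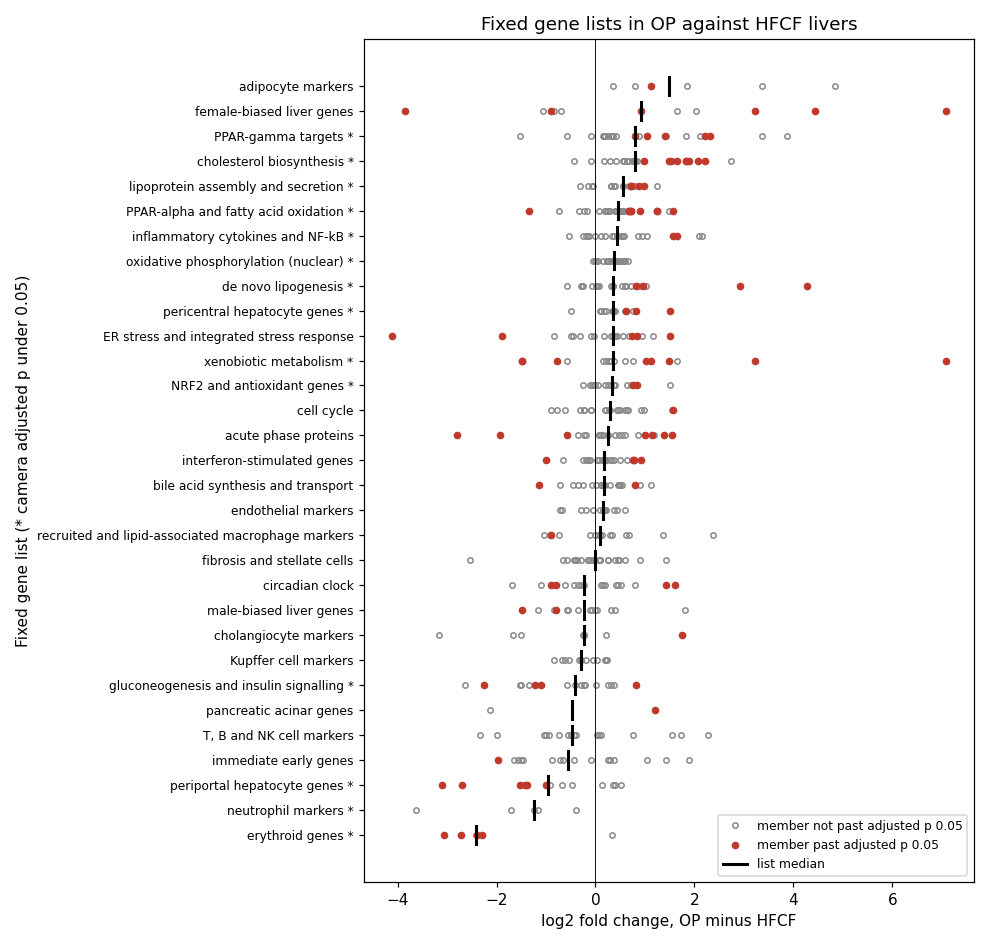
log2 fold change (OP minus HFCF) of each tested member of the 31 fixed lists, red where the adjusted p was under 0.05, with the list median as a black bar and an asterisk for a camera adjusted p under 0.05; Hao2 and Cyp2b13, at 0 in HFCF, are drawn at their lower bounds. Medians ran from -2.41 for erythroid genes to 1.49 for adipocyte markers.

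Of 19 clock genes 2 rose and 2 fell, against 4 and 4 adjusted over the list alone. Per2 rose from 31.3 ± 2.18 to 95.6 ± 32.9 CPM and Wee1 from 4.42 ± 0.694 to 11.95 ± 1.005 CPM, while Cry2 (-0.90) and Nr1d1 (-0.79) fell, and the list's camera adjusted p was 0.609. Nr1d1 overlaps Thra on the opposite strand, which fell by 0.79 too, and it lost its call whichever library was left out (-0.90 to -0.63). Ccnd1, the cyclin of the G1 phase, rose from 9.55 ± 1.12 to 28.2 ± 2.93 CPM and was the 1 cell cycle gene of 22 that passed, also adjusted over the list alone (camera adjusted p = 0.12). Junb fell from 45.3 ± 20.5 to 11.5 ± 1.17 CPM, the 1 immediate early gene of 16 that passed, against 2 lower adjusted over the list alone (camera adjusted p = 0.389). Ccnd1 kept its call whichever library was left out, Wee1 lost it without HFCF replicate 2, Junb without HFCF replicate 1 or OP replicate 1, Per2 (1.43 to 1.87) without HFCF replicate 1, HFCF replicate 2 or OP replicate 1 and Cry2 without any library but OP replicate 3.

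Camera with its preset correlation called 14 of 30 lists, 10 higher and 4 lower. With an estimated correlation it called 0 (smallest adjusted p 0.647, 0 at an unadjusted p under 0.05), and the fry test also called 0 (smallest adjusted p 0.0559, 12 at an unadjusted p under 0.05), while camera on ranks called 14. With the mitochondrial share as a covariate, 4 of the 14 lists kept their call, for gluconeogenesis and insulin signalling, erythroid, pericentral and periportal genes. Their medians were then -0.42, -2.395, 0.42 and -1.58. The periportal median was larger in size than the -0.96 without the covariate (camera adjusted p = 9.12e-08 with it). Medians of lists that lost their call and are not given above were 0.30 for lipoprotein genes, 0.44 for inflammatory genes, -0.63 for neutrophil markers and 0.33 for xenobiotic enzymes, with camera adjusted p of 0.0657, 0.155, 0.657 and 0.657. Of the 89 named genes that had passed, 30 kept their call with this covariate.

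Composition was compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. Mitochondrially encoded mRNAs took 22.0%, 18.8% and 14.1% of counts in the HFCF libraries and 7.48%, 6.08% and 14.4% in the OP libraries, so the groups overlapped (18.3 ± 4.01% and 9.31 ± 4.44%, exact permutation p = 0.2). The mitochondrially encoded mt-Nd6, an abundant gene that passed the test, fell by 1.66 on the log2 scale, and lost its call without HFCF replicate 1, HFCF replicate 2, OP replicate 1 or OP replicate 2 (-2.20 to -1.40). Mitochondrial rRNAs took 0.183 ± 0.0297% and 0.376 ± 0.178% (exact permutation p = 0.1), with no overlap between the groups, the opposite direction to the mRNAs. OP replicate 3 was the highest, at 0.580%. Globin genes took 0.129 ± 0.0444% and 0.0215 ± 0.0121% of counts (exact permutation p = 0.1), albumin 2.19 ± 1.05% and 4.14 ± 1.25% (exact permutation p = 0.2), and the 10 most abundant genes 20.7 ± 2.54% and 18.4 ± 1.97% (exact permutation p = 0.3). Total counts did not pass either (exact permutation p = 0.5).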

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

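The covariate, total-count, mitochondrial-gene and divided-count alternatives were chosen after seeing the data. No gene called between OP and HFCF changed sign under any of the gene-level alternatives run. This was likely from the outset, since all 1170 called genes had OP libraries that did not overlap the HFCF libraries. The genes higher in OP and genes lower in OP, 567 and 603, were 72 and 92 at an adjusted p of 0.01, 1322 and 1230 at 0.1, 234 and 358 at a fold change of at least 2, 298 and 400 with no low-count filter (more genes tested), 1269 and 1265 with DESeq2, 1820 and 1539 with quality weights, and 110 and 97 with the mitochondrial share as a covariate; apart from those set by the thresholds and the filter, the cause was not tested. Leaving out single libraries gave 34 to 655 higher and 54 to 655 lower genes, more than 567 higher without HFCF replicate 3 or OP replicate 3, and the cause was not tested; 19 of the 89 named genes that were called kept their call whichever library was left out. The share of higher among called genes was 48.5%, and 42.6% to 45.3% with other scalings, with the median of all genes within 0.1 of 0. Named genes that lost a call numbered 2 with RLE scaling, 7 with total counts, 18 with no low-count filter, 5 with robust dispersion, 4 with limma-voom and 59 with the covariate, and 8 gained one with DESeq2 and 10 with quality weights. Lists called, 14, were 0 with an estimated correlation, 0 by fry, 4 with the covariate and 12 to 16 without single libraries. The PPAR-gamma median of 0.80 had an adjusted p of 0.647 by camera with an estimated correlation and of 0.0678 by fry, which compares the list with no other genes (over its alternatives 0.000141 to 0.647); it was 0.32 with the covariate (0.098), and 0.37 to 0.91 without single libraries. The difference in mitochondrial mRNA share, -8.98 percentage points, was -11.5 to -7.11 without single libraries. Signs changed with the covariate for the medians of the bile acid (-0.088), acute phase (-0.25), cell cycle (-0.20) and oxidative phosphorylation (-0.064, the 1 called list among them) lists, and for Scd1 (-1.001), Lpl (-1.54), Acta2 (-0.63) and Stab2 (0.31); with limma-voom for the fibrosis median (0.099), Col1a1 (0.17) and Lpl (-0.13); with quality weights for Tnf (-0.11) and Lpl (-0.15). Without single libraries values crossed 0 for the medians of fibrosis (-0.35 to 0.26), recruited macrophage (-0.059 to 0.23) and endothelial genes (-0.020 to 0.17), and for Col1a1 (-0.55 to 0.57), Tnf (-0.12 to 0.44), Lpl (-1.08 to 0.78) and Acta2 (-0.20 to 0.96). Depth limits the genes near 0.05 CPM.

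Replicate numbers are shared by both groups, but same-numbered samples deviated from their group means with correlations of 0.0229, -0.126 and -0.164, and not every sample correlated best with its own number. These values gave no sign of pairing. So few correlations cannot exclude a shared day or litter, and the labels do not say what the numbers mean. With the replicate number as a block the counts were 87 higher and 93 lower and 15 lists were called, 50 named genes lost a call and 1 gained one, and the fibrosis median and Col1a1 were each 0.056 and Lpl -0.19.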

Other observations

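The tests of the nuclear copies, the respiratory chain, time of day, the fatty acid oxidation genes and the immediate early genes were chosen only after the results were seen. Among 10 chaperone genes of the heat shock factor 1 type, listed after Hspa1a, Hspa1b and other heat shock genes had been seen but before their own values were, 6 rose and none fell, including Hsph1 from 17.8 ± 1.07 to 74.5 ± 28.5 CPM, Hspa8 from 732 ± 52.8 to 1381 ± 151 CPM and Dnaja1 from 136 ± 10.2 to 260 ± 17.8 CPM (n = 3 libraries per group, edgeR's quasi-likelihood test). Hsph1 lost its call without HFCF replicate 1 or 2 (1.73 to 2.29 on the log2 scale), and Hspa8 and Dnaja1 without these or OP replicate 1. Cirbp, the cold-inducible RNA-binding protein, fell from 57.0 ± 5.74 to 17.1 ± 3.77 CPM, and Rbm3, a related cold-inducible gene, was at 62.2 ± 2.83 and 48.9 ± 7.49 CPM without passing the test. Antisense genes had a median log2 fold change of -0.31, with 10 higher and 29 lower, against 0.03 for protein-coding genes, with 522 and 500. Genes of the annotation class TEC had a median of -0.32, with 1 higher and 15 lower. By transcript length, medians ran from 0.086 in the shortest quintile to -0.094 in the longest, where 82 genes were higher and 154 lower. The cause of these differences was not tested.

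Higher heat shock genes with lower Cirbp may reflect a difference in temperature of the animals or tissue. The 10 chaperones had a median log2 fold change of 0.77 ± 0.203 (camera p = 2.36e-06, and p = 0.0325 with an estimated correlation), above the 0.5 this explanation needed, with Rbm3 at -0.35 but not past the test. Here and below, the SE of a median is a spread over genes and not over libraries. Any cause that activates heat shock factor 1 would raise these chaperones. Their rise therefore cannot tell temperature from other causes. Stress of dissection or handling would raise immediate early genes, and their median was -0.55 ± 0.366, with 6 of 16 members above 0 and -0.088 without HFCF replicate 3, which leaves it undecided. A response of the liver to the treatment itself was not tested and stays open, since temperature was not recorded in the labels.

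Lower Sds, Hal and Sdsl, enzymes of amino acid breakdown, may reflect a difference in feeding state at tissue collection. The 24 fasting-induced genes outside the fixed lists had a median of -0.34 ± 0.265 (camera p = 0.0189, and p = 0.215 with an estimated correlation), which goes with it, though 16 feeding-induced genes had a median of -0.088 ± 0.3 and the 13 fasting-induced genes of fatty acid oxidation and ketone synthesis one of 0.41 ± 0.265, which leaves those genes undecided. Fewer periportal hepatocytes in the OP pieces would lower the 6 periportal genes that are not amino acid enzymes. Their median was 0.24 ± 0.212, with 1 below 0 (camera p = 0.34, and p = 0.648 with an estimated correlation). These genes did not fall as a set, but the SE is a spread over genes and not over libraries. Since 13 of 14 pericentral genes also lay above 0, a shift in hepatocyte zones stays undecided. For time of day, the medians of clock genes of opposite phase differed by -0.00981 ± 0.582, too wide a spread to decide. The treatment as a cause was not tested and stays open.

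All 13 mitochondrially encoded mRNAs had negative log2 fold changes (median -0.97), of which mt-Nd6 alone passed. Scaling between libraries is argued against, since the median lay between -1.02 and -0.97 under 5 scalings. Lower expression of the respiratory chain as a whole stays undecided. Its nuclear genes did not fall as a set, with a median of 0.37 and 22 of 24 above 0. These genes moved together (estimated correlation 0.684), and the fry test gave an unadjusted p = 0.114. Their median was therefore not told apart from the spread between libraries. Poorer capture of RNA with short poly(A) tails stays undecided. The 25 replication-dependent histone genes had a median of 0.28 ± 0.299, but they lack a tail and so do not report the capture of short tails. Reads lost to nuclear copies are argued against too, since the share of the copies differed by -2.13 percentage points between OP and HFCF (5.45 ± 1.09% in HFCF and 3.32 ± 1.36% in OP), in the direction of the mRNAs (-8.98), and mRNAs and copies together had a log2 ratio of -0.911. Mitochondrial rRNAs went the opposite way, at 0.183 ± 0.0297% of counts in HFCF and 0.376 ± 0.178% in OP. Much of this difference came from OP replicate 3 (0.580%, against 0.255% in OP replicate 1 and 0.293% in OP replicate 2). An effect of the treatment was not tested and stays open.

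The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1170 genes, as many as in 1 of the 10 splits counting itself, and the highest other split called 2. It called 14 gene lists, and 2 of the 10 splits, itself included, called as many, the highest other also calling 14.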
